A study of Arabidopsis thaliana with 12 samples.

How the data were processed

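RNA was measured in 12 libraries from dark-grown Arabidopsis seedlings, 3 in each of 4 groups: wild type Col-0 and the double mutant b''ab''b, kept in the dark or given 1 h of red light. The deposited table holds whole-number counts per gene and library, which per the labels come from 3′ tag libraries made from total RNA. The submitters' processing notes name FastQC, HISAT2, HTSeq, edgeR and the genome build TAIR10, without versions, settings or roles. Strand settings, the handling of reads that match several genes and any filtering before counting are not given in the sources used here. The table has 33655 genes, of which 32548 carry locus identifiers, and all 32548 matched the TAIR10.1 annotation, which supplied gene names and positions, so printed coordinates are those of TAIR10.1 for the same locus. Another 1107 identifiers are of other kinds and were kept under the identifiers given, and 7717 genes had no count in any library. The 5 HTSeq summary lines at the end of the table were left out. The line of reads without a unique match is broken across lines, and its values (1485815 to 4510380) could not be assigned to libraries. Each column was matched to a sample by its name and that sample's title.

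Totals ran from 2874429 to 4979055 counts per library. The 10 most abundant genes took 5.16 to 6.12% of the counts and reads that fell on more than 1 gene came to 0.943 to 1.28% of the gene counts. At this depth 3 counts, the most that a count of 0 allows, correspond to 0.603 to 1.04 CPM. Tag libraries without molecular identifiers count PCR copies as separate reads, so this limit covers counting error only. For every pair of replicates in a group, counts differed by more than sampling noise (lowest chi-square per degree of freedom 1.55), so each library was counted as its own sample.

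Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, genes kept by filterByExpr (minimum count 10, 18487 genes), 1 quasi-likelihood fit over all 12 libraries with a term per group, and Benjamini-Hochberg adjusted p under 0.05. The median standard error of a log2 change between groups was 0.174. Contrasts were red minus dark in each genotype, double mutant minus wild type in the dark and in red light, the difference between the red light responses, the mean red light response and the mean genotype difference. The standard error printed beside a log2 change is its size divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry on voom values in limma 3.58.1, adjusted over the lists of 1 comparison. Camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, in 1 direction. Calls by camera for light signalling, PIF-activated, light-harvesting, photosystem, clock, flavonoid, touch and heat shock genes in both red light responses held with an estimated correlation. The light-regulated sets were genes called in the mean red light response with a change of at least 1 on the log2 scale. In this balanced design the error of the mean response is independent of that of the interaction. With a library of 1 genotype left out this no longer holds, so picking the genes anew can itself shift the median interaction. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

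The groups, tests, 21 gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for each of the first 5 contrasts, the B''α and B''β genes, up to 6 genes with the largest rise and up to 6 with the largest fall among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups, up to 4 called members with the smallest p from each list, and 18 well-known light response genes (HY5, PIL1, HFR1, ATHB2, IAA19, XTH15, ELIP1, ELIP2, HEMA1, GUN5, PORA, CCA1, PHYA, PIF1, PIF3, PIF4, PIF5 and CHS). Other genes named are said to have been chosen after their values were seen. The lists cover PP2A subunits, phytochromes and PIFs, light signalling, PIF-activated genes, light-harvesting proteins, photosystems and Rubisco, chlorophyll synthesis, clock, flavonoids, auxin, gibberellin, brassinosteroid, ethylene, wall loosening, mevalonate and sterols, touch and jasmonate, heat shock, seed stage, root hair, endodermis and dividing cells, the last 4 as markers of stage or cell type. A list needed 5 tested members, and the numbers given are over members that passed the filter on low counts (7 of 13 for heat shock, 18 of 26 for touch, wound and jasmonate and 11 of 18 for seed stage).

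Alternatives set from the start were DESeq2 1.42.0 or limma-voom in place of edgeR, RLE factors in place of TMM, no filter on low counts, a mean of at least 5 CPM, the replicate number as a block, only the 2 groups compared, an estimated correlation for lists, and each library left out in turn. Leaving out the 2 dark libraries that stand apart and thinning all libraries to the smallest total were added after seeing the data. The filter on low counts was redone for each reduced set of libraries. A call lost without a library can therefore come from the changed filter as well as from that library. The added lists (phosphate starvation, greening regulators, carotenoids, plastid isoprenoids, unfolded protein response, ABA and late embryogenesis) were also drawn up after seeing the data.

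The procedure was tested on simulated counts with 200 changed genes. For the wild type red light response (18208 genes) edgeR recovered 34.3, 71.6 and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 11 false calls. For the genotype difference in the dark (18219 genes) it recovered 41.8, 82.1 and 97.0%, with 7 false calls, and for the interaction (18223 genes) 14.9, 47.8 and 83.3%, with 7 false calls. Among 20 simulated lists (18249 genes, wild type red light response) the changed list was called by camera with both correlations and by fry (adjusted p = 4.86e-76, 6.97e-07 and 5.09e-08 with limma) and 0 unchanged lists were. Simulated genes varied independently of one another. The absence of false list calls therefore does not carry over to lists whose genes vary together, such as the photosystem list (estimated correlation 0.355 in the wild type response). A simulated median interaction of −1 among 700 light-raised genes (18251 genes) was estimated as −0.996 over the 698 that were found.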

Results

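Transcripts were counted in whole seedlings of Arabidopsis thaliana that had grown for 4 days in the dark at 22 °C. Before that the seeds had 3 days of cold and 3 h of white light at 25 µmol per square metre per second. Seedlings of the wild type Col-0 and of the double mutant b''ab''b, named for the B''α and B''β regulatory subunits of protein phosphatase 2A (PP2A), either stayed in the dark or received 1 h of continuous red light at 8 µmol per square metre per second. Each of the 4 groups held 3 libraries, which gives 12 libraries of 3′ tags from total RNA, a method in which each read comes from near the 3′ end of a transcript. The libraries held 2874429 to 4979055 counts, and 18487 genes had enough counts to be tested. A gene with no reads in a library could still hold up to 3 counts, which is 0.603 to 1.04 CPM (counts scaled to library size), counting error only. The labels do not say whether the 3 replicates of a group were grown as separate cultures, so p-values measure the spread between these samples, which may be technical.

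Red light separated the libraries most. The first principal component held 46.7% of the variance and had all 6 dark libraries on the negative side and all 6 red light libraries on the positive side. The second component held 9.92% and set 2 dark libraries apart, wild type replicate 1 (score 27.6) and double mutant replicate 3 (score 25.0), while the other 4 dark libraries scored from −20.2 to −8.15. Of the red light libraries, wild type replicate 2 (11.2) and double mutant replicate 3 (13.2) also scored high, and the others from −7.84 to 1.21. The common biological coefficient of variation was 0.0875, and no pair of replicates within a group was as close as counting noise alone allows.

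Transcripts of the B''α gene (AT5G44090, chromosome 5, 17742765 to 17748526 in TAIR10.1) were lower in every double mutant library than in every wild type library. B''α stood at 24.4 to 31.2 CPM in the 6 wild type libraries and at 3.88 to 6.29 CPM in the 6 double mutant libraries. In the dark it was 4.74-fold lower in the mutant (log2 fold change −2.24 ± 0.16 SE, n = 3 per group, edgeR adjusted p = 2.63e-08), and in red light 6.76-fold lower (−2.76 ± 0.18, edgeR adjusted p = 1.53e-09). The B''β gene (AT1G03960, chromosome 1, 1013643 to 1017957) was close to the detection limit, with 8 to 20 counts per wild type library and 3 to 9 per double mutant library. Its mean in the dark was 4.19 ± 0.671 CPM in the wild type and 1.099 ± 0.252 CPM in the mutant (SD, n = 3), a difference that did not pass over all genes with edgeR (log2 −1.87 ± 0.42, adjusted p = 0.226) and passed without the filter on low counts (log2 −1.86, adjusted p = 0.0308). In red light the B''β means were 2.76 ± 0.819 and 1.398 ± 0.656 CPM (edgeR adjusted p = 0.999). The insertion or deletion sites are not given in the sources used here, and a tag outside a disrupted part checks nothing, so these counts show less RNA 3′ of B''α and say little on B''β.

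**Figure D1:**
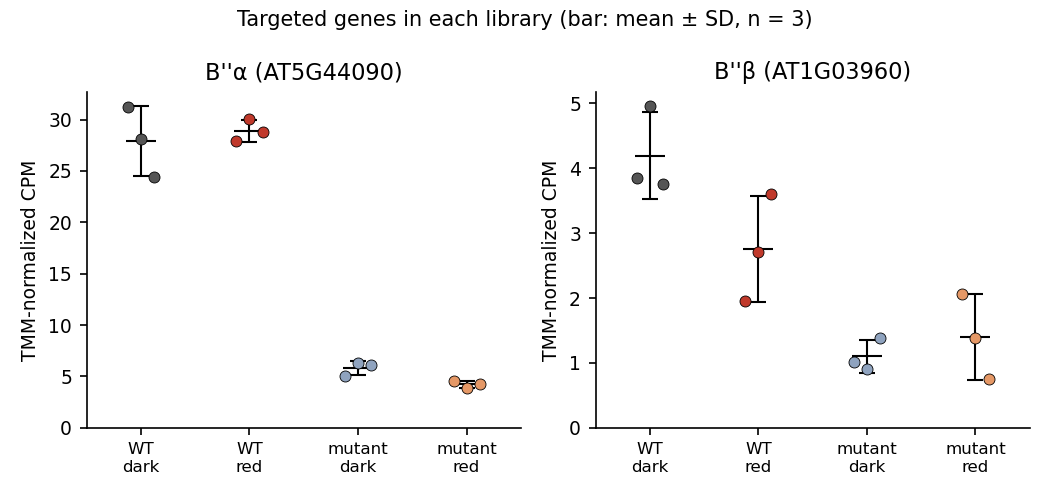
CPM of the B''α and B''β genes in each of the 12 libraries (points), with the mean ± SD of each group (n = 3), by genotype and light. B''α lies at 24.4 CPM or more in the wild type and at 6.29 CPM or less in the double mutant.

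The first question was what 1 h of red light does to the transcripts of dark-grown wild type seedlings. The B-box regulator BBX32 (AT3G21150) rose most among the named genes, from 1.47 ± 0.651 to 66.1 ± 9.73 CPM (SD, n = 3; log2 5.51 ± 0.24 SE, edgeR adjusted p = 2.62e-14). In that comparison the B-box gene BBX16 rose 27.0-fold (log2 4.75 ± 0.18) and the chaperone gene HSP70 (AT3G12580) 19.5-fold (4.29 ± 0.12). Among abundant genes (mean log2 CPM of at least 3) without overlap between libraries there followed the clock coactivator gene LNK1 17.41-fold (4.12 ± 0.16), AT1G48100 16.7-fold (4.06 ± 0.19) and CGA1, a GATA factor of chloroplast development, 16.0-fold (4.00 ± 0.25). The largest falls under the same limits were in GRF7 (AT5G53660), a growth-regulating factor (15.2-fold lower, log2 −3.92 ± 0.16, 76.0 to 4.98 CPM), and AT5G44260 (8.50-fold lower). Then followed the small peptide gene RTFL21 (7.08-fold lower), HLS1, which keeps the apical hook closed (6.87-fold lower), RAV1 (6.42-fold lower, 169 to 26.4 CPM) and the B-box gene BBX17 (5.48-fold lower). In total 1954 genes rose and 865 fell of 18487 (edgeR, adjusted p under 0.05), of which 725 and 212 changed by at least 1 on the log2 scale. The rule that picked the 12 genes above required no overlap between the 3 red light and the 3 dark libraries.

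Regulators of light signalling rose as a group in the wild type: 14 of 20 measured members rose and 3 fell (15 and 3 adjusted over the list alone), with a median log2 change of 1.61 (camera adjusted p = 3.84e-13, and 3.95e-04 with an estimated correlation). HY5 (AT5G11260), a factor that promotes photomorphogenesis, rose from 33.6 ± 1.90 to 175 ± 1.65 CPM (log2 2.39 ± 0.10), BBX24 rose by 2.40 ± 0.07 and BBX31 by 5.50 ± 0.28. Among 13 phytochromes and PIFs (phytochrome-interacting factors), 4 rose and 3 fell (5 and 3 adjusted over the list alone). PIF4 rose by 1.98 ± 0.14, PIF5 by 1.89 ± 0.10 and PIF8 by 1.46 ± 0.13. FHY1 (AT2G37678), which carries phytochrome A into the nucleus, fell by 1.90, PHYA itself fell by 0.53 and PIF3 fell by 0.57. PIF1 did not pass (log2 −0.11 ± 0.13, edgeR adjusted p = 0.651). That list had a negative median (−0.09), a positive mean (0.26) and no call by camera (adjusted p = 0.562). Fry placed its genes, on balance, upward (adjusted p = 5.64e-04).

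Shade and growth genes known to be activated by PIFs fell: 11 of 16 measured members fell and 0 rose (11 and 1 adjusted over the list alone), with a median of −0.96 (camera adjusted p = 9.96e-10, and 0.00237 with an estimated correlation). PIL1 was 11.3-fold lower (log2 −3.50 ± 0.26), the homeobox gene ATHB2 4.62-fold lower (−2.21 ± 0.23), PAR1 3.17-fold lower (−1.66 ± 0.09) and the cell wall enzyme gene XTH15 2.41-fold lower (−1.27 ± 0.11). HFR1, a brake on PIF activity, stood at log2 0.32 ± 0.11 and missed the threshold (edgeR adjusted p = 0.0612), passing without wild type dark replicate 1 (0.43, adjusted p = 0.0251) or double mutant dark replicate 3 (0.33, 0.0470).

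Genes of the photosynthetic apparatus rose together by small amounts in the wild type. All 20 light-harvesting genes rose (20 adjusted over the list alone), with a median log2 change of 0.38 (camera adjusted p = 1.09e-22, and 0.00764 with an estimated correlation). The early light-induced genes ELIP1 (329 ± 40.9 to 1375 ± 53.3 CPM, log2 2.06 ± 0.09) and ELIP2 (1.38 ± 0.07) moved most, followed by LHCB4.3 (1.19 ± 0.11). LHCB3 rose by 0.51 ± 0.05. Of 26 photosystem and Rubisco genes 24 rose and 0 fell (26 rose adjusted over the list alone), with a median of 0.28 (camera adjusted p = 2.88e-16, and 0.0450 with an estimated correlation). PSBS, needed to shed excess light energy, rose by 0.62 ± 0.07 and PSBR by 0.28 ± 0.05. Chlorophyll synthesis was mixed, with 6 of 24 genes higher and 2 lower (6 and 2 adjusted over the list alone), a median of −0.02, a mean of 0.05 and no call for the list (camera adjusted p = 0.597). Within it HEMA1, which encodes the rate-limiting step of tetrapyrrole synthesis, rose by 0.68 ± 0.08 and the chelatase gene GUN5 by 0.65 ± 0.07. PORA and PORB, protochlorophyllide reductases abundant in dark-grown tissue, fell by 0.59 and 0.60. Members of the LHCB1 and Rubisco small subunit families are near copies of one another, as are neighbouring SAUR genes. How reads matching several genes were counted is not given in the sources used here, so the division of counts within these families is uncertain.

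Clock and flavonoid genes also rose. Of 22 clock genes 16 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 1.94e-17, and 3.95e-04 with an estimated correlation). GI rose by 3.25 ± 0.20, CCA1 by 1.75 ± 0.09 (49.9 ± 1.99 to 168 ± 10.2 CPM) and LNK2 by 1.63 ± 0.08. Of 13 flavonoid genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.098 (camera adjusted p = 8.70e-11, and 0.00205 with an estimated correlation). F3H rose 7.29-fold (log2 2.87 ± 0.16), CHI (AT3G55120) 2.96-fold (1.56 ± 0.14) and CHS, the entry enzyme, 1.57-fold (0.65 ± 0.08).

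Hormone and wall genes moved in both directions. Among 36 auxin response genes 8 rose and 12 fell (10 and 13 adjusted over the list alone; camera adjusted p = 0.519). SAUR14 (2.62 ± 0.12), SAUR6 (2.05 ± 0.10) and GH3.6 (0.91 ± 0.11) rose, while IAA19 fell by 0.80 and IAA4 by 0.63. The list's median was −0.02 and fry placed it upward without a call (adjusted p = 0.516). Of 17 gibberellin genes 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.159). The gibberellin-inactivating GA2OX1 went from 0.468 ± 0.424 to 14.9 ± 2.88 CPM and GA2OX2 from 4.53 ± 0.822 to 15 ± 2.42 CPM. The synthesis gene GA3OX2 went from 0.610 ± 0.627 to 5.85 ± 2.04 CPM, and the repressor GAI fell by 0.86. Of 14 ethylene genes 1 rose and 6 fell (2 and 6 adjusted over the list alone), with a median of −0.37 (camera adjusted p = 0.00130, and adjusted p = 0.148 with an estimated correlation). HLS1 fell by 2.78 and the F-box gene EBF2 by 0.91, while its relative EBF1 rose by 0.64 ± 0.09. Of 14 brassinosteroid genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; median 0.05, mean −0.12, camera adjusted p = 0.953), led by BEE3 (−2.16 ± 0.38). Of 26 wall-loosening genes 11 rose and 6 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.267). Fry placed the wall-loosening and gibberellin lists, on balance, upward (adjusted p = 2.86e-04 and 0.00198). The expansins EXPA1 (2.098 ± 0.09) and EXPA10 (1.34 ± 0.13) and the xyloglucan enzyme gene XTH32 (1.32 ± 0.10) rose, and XTH15 fell.

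Heat shock and touch genes were higher in the red light libraries of the wild type. Of 13 heat shock genes listed 7 had enough counts to be tested. Of these 7, 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 3.19 (camera adjusted p = 9.24e-11, and 0.00588 with an estimated correlation). HSP90.1 rose from 3.82 ± 0.958 to 35.9 ± 3.43 CPM (log2 3.19 ± 0.18), HSP101 by 2.59 ± 0.16 and HSP17.8 by 3.93 ± 0.26. Of 18 touch, wound and jasmonate genes 7 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.86e-04, and 0.01 with an estimated correlation). Among them were the zinc finger genes ZAT12 (1.76 ± 0.17) and ZAT6 (1.75 ± 0.24), the calmodulin-like TCH2 (0.82 ± 0.09) and the jasmonate regulator MYC2 (0.77 ± 0.10). No member passed over all genes with edgeR among 27 PP2A subunit genes (median −0.06, camera adjusted p = 0.303), 8 root hair markers (−0.16, 0.427), 7 endodermis markers (0.14, 0.367) and 9 markers of dividing cells (median 0.00, mean −0.02, 0.783). Of 16 mevalonate and sterol genes HMGS alone passed (log2 −0.24 ± 0.08, edgeR adjusted p = 0.0373; camera adjusted p = 0.269 for the list), a call that ended with DESeq2 (0.0992) and without any of 10 libraries (0.0505 to 0.142). Of 11 seed stage genes 0 rose and 2 fell (median −0.24, mean 0.11, camera adjusted p = 0.427), MLS (log2 −0.44 ± 0.12, adjusted p = 0.0164) and PCK1 (−0.24 ± 0.08, 0.0497), with neither called by DESeq2 (0.0953 and 0.0565).

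The second question was how the double mutant responds to the same light. BBX32 rose from 1.08 ± 0.243 to 54.6 ± 9.32 CPM (SD, n = 3; log2 5.67 ± 0.25 SE, edgeR adjusted p = 4.83e-14). BBX16 rose 28.2-fold (4.82 ± 0.19), LNK1 20.9-fold (4.38 ± 0.17), HSP70 19.0-fold (4.24 ± 0.11), AT1G48100 18.4-fold (4.202 ± 0.19) and ABCI21 17.9-fold (4.16 ± 0.10, 16.98 to 309.6 CPM). GRF7 was 15.69-fold lower (log2 −3.97 ± 0.17), AT5G44260 11.4-fold lower, RTFL21 8.02-fold lower, RAV1 6.52-fold lower, BBX17 6.39-fold lower and AT1G60060 5.77-fold lower. In total 1983 genes rose and 975 fell of 18487 (edgeR, adjusted p under 0.05), of which 714 and 226 changed by at least 1 on the log2 scale.

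The gene lists moved in the double mutant as follows. Light signalling regulators had 14 of 20 higher and 3 lower (14 and 3 adjusted over the list alone; median 1.70, camera adjusted p = 1.65e-11), with HY5 at 2.39 ± 0.10 and the COP1 partner SPA1 at 1.70 ± 0.09. Phytochromes and PIFs had 6 of 13 higher and 4 lower (6 and 4 adjusted over the list alone; median −0.06, mean 0.30, camera adjusted p = 0.460), with PIF4 at 1.59 ± 0.14, PIF5 at 2.02 ± 0.10 and PHYA at −0.58 ± 0.07. PIF-activated genes had 1 of 16 higher and 11 lower (1 and 11 adjusted over the list alone; median −0.87, camera adjusted p = 4.86e-10), with PIL1 at −3.39 ± 0.26, ST2A at −1.603 ± 0.16 and, as the 1 that rose, HFR1 at 0.50 ± 0.11. All 20 light-harvesting genes rose (20 adjusted over the list alone; median 0.46, camera adjusted p = 7.23e-26), with ELIP1 at 2.101 ± 0.09 and LHCA1 at 0.70 ± 0.06. Of 26 photosystem and Rubisco genes 24 rose and 0 fell (26 and 0 adjusted over the list alone; median 0.36, camera adjusted p = 5.34e-21), with PSBS at 0.72 ± 0.07. Clock genes had 16 of 22 higher and 1 lower (17 and 1 adjusted over the list alone; median 1.31, camera adjusted p = 2.33e-17), with GI at 3.37 ± 0.20. Flavonoid genes had 11 of 13 higher and 0 lower (11 and 0 adjusted over the list alone; median 1.34, camera adjusted p = 6.26e-12), with 4CL3 at 2.46 ± 0.23. Each of these calls by camera held with an estimated correlation, with adjusted p from 4.77e-04 for the clock to 0.0232 for the photosystem list.

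Stress genes rose in the double mutant too: 6 of 7 heat shock genes rose and 0 fell (7 and 0 adjusted over the list alone; median 3.69, camera adjusted p = 1.69e-11, and 0.00509 with an estimated correlation), with HSP90.1 at 3.69 ± 0.17. Of the touch genes 6 of 18 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.42, camera adjusted p = 0.00202, and 0.0232 with an estimated correlation), with ZAT12 at 1.63 ± 0.17. Chlorophyll synthesis had 6 of 24 higher and 2 lower (7 and 2 adjusted over the list alone; median 0.09, camera adjusted p = 0.0282). The adjusted p was 0.370 with an estimated correlation, 0.116 without double mutant dark replicate 3, 0.113 without double mutant red replicate 2 and 0.0830 without the 2 dark libraries that stand apart. Gibberellin genes had 5 of 17 higher and 1 lower (5 and 1 adjusted over the list alone, median 0.20, camera adjusted p = 0.0438), with adjusted p = 0.102 with an estimated correlation and from 0.0642 to 0.188 without any of the 12 libraries in turn. The camera adjusted p was 0.0618 without the filter on low counts, so these losses cannot be tied to single libraries. Fry placed the gibberellin and wall-loosening lists, on balance, upward in the double mutant (adjusted p = 3.19e-04 and 1.46e-04). Ethylene genes had 1 of 14 higher and 7 lower (2 and 7 adjusted over the list alone; median −0.26, camera adjusted p = 0.00108), with adjusted p = 0.114 with an estimated correlation, and HLS1 at −2.05 ± 0.26. Camera called neither auxin (8 of 36 higher and 11 lower, 9 and 14 adjusted over the list alone, adjusted p = 0.401) nor wall-loosening genes (9 of 26 higher and 5 lower, 10 and 7 adjusted over the list alone, 0.137) nor brassinosteroid genes (2 of 14 higher and 2 lower, both ways also adjusted over the list alone, median 0.01, mean −0.14, 0.890). IAA29 stood at −1.92 ± 0.22, IAA20 at −1.54 ± 0.16, EXPA1 at 2.07 ± 0.09 and BEE3 at −2.25 ± 0.39. Among 27 PP2A genes PP2AA3 (log2 0.33 ± 0.11, edgeR adjusted p = 0.0465) and PP2A4 (−0.25 ± 0.08, 0.0440) passed over all genes and 0 passed adjusted over the list alone. DESeq2 called neither (0.141 and 0.0705; camera adjusted p = 0.137 for the list). PCK1 alone passed among 11 seed stage genes (−0.31 ± 0.08, edgeR adjusted p = 0.00790, and 0.0718 without double mutant dark replicate 3; median −0.05, mean 0.31, camera adjusted p = 0.824). With edgeR 0 members passed among the mevalonate (camera adjusted p = 0.137), root hair (0.348), endodermis (0.666) and dividing cell lists (0.890).

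Side by side, the responses of the genotypes overlapped. Of the called genes, 1591 rose in both genotypes and 546 fell in both, where independent lists would share 210 and 45.6, and 0 were called in opposite directions by edgeR. A further 682 genes were called in the wild type alone, of which 656 had the same sign in the double mutant, and 821 in the double mutant alone, of which 780 had the same sign in the wild type. Across all genes tested the log2 changes had Pearson's r = 0.80 and Spearman's rho = 0.63. Genes are not independent replicates, so no p-value is given. HY5 (2.39 and 2.39), CCA1 (1.75 and 1.75) and ELIP2 (1.38 and 1.405) had near-equal changes in wild type and double mutant.

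**Figure D2:**
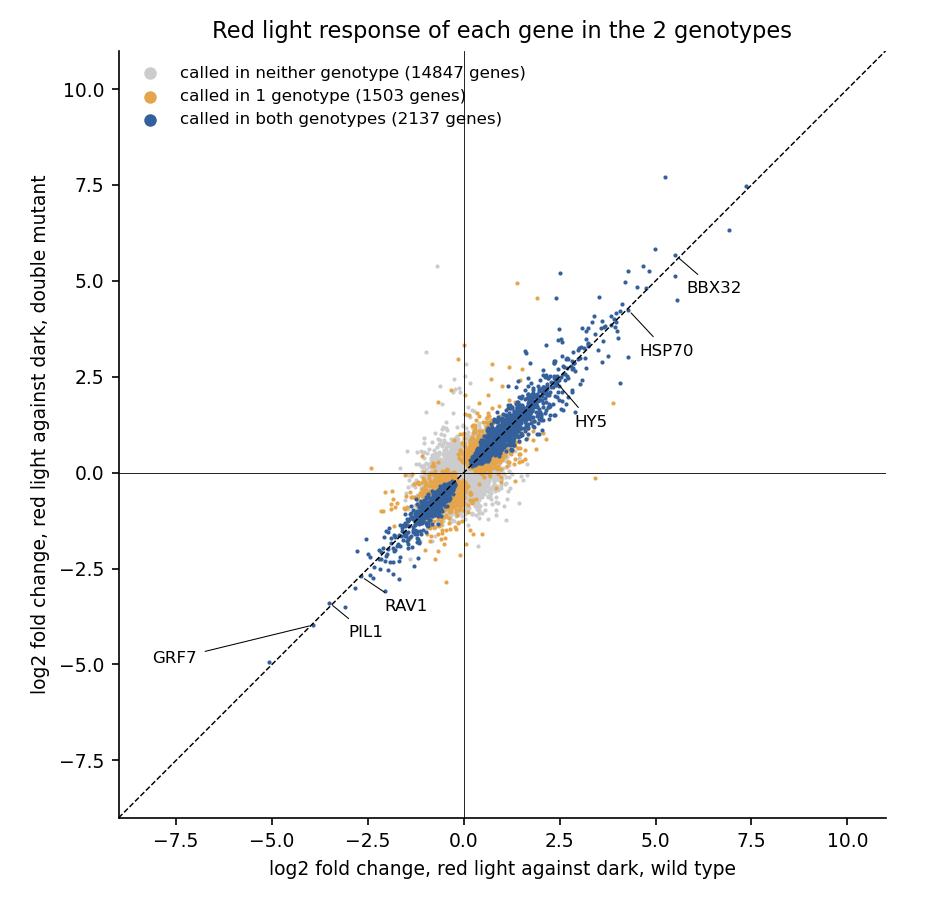
Log2 change with red light in the double mutant (vertical axis) against that in the wild type (horizontal axis), with 1 point per gene tested, coloured by whether edgeR called it in neither genotype (14847 genes), in 1 genotype (1503) or in both (2137). No gene is called in opposite directions.

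**Figure D3:**
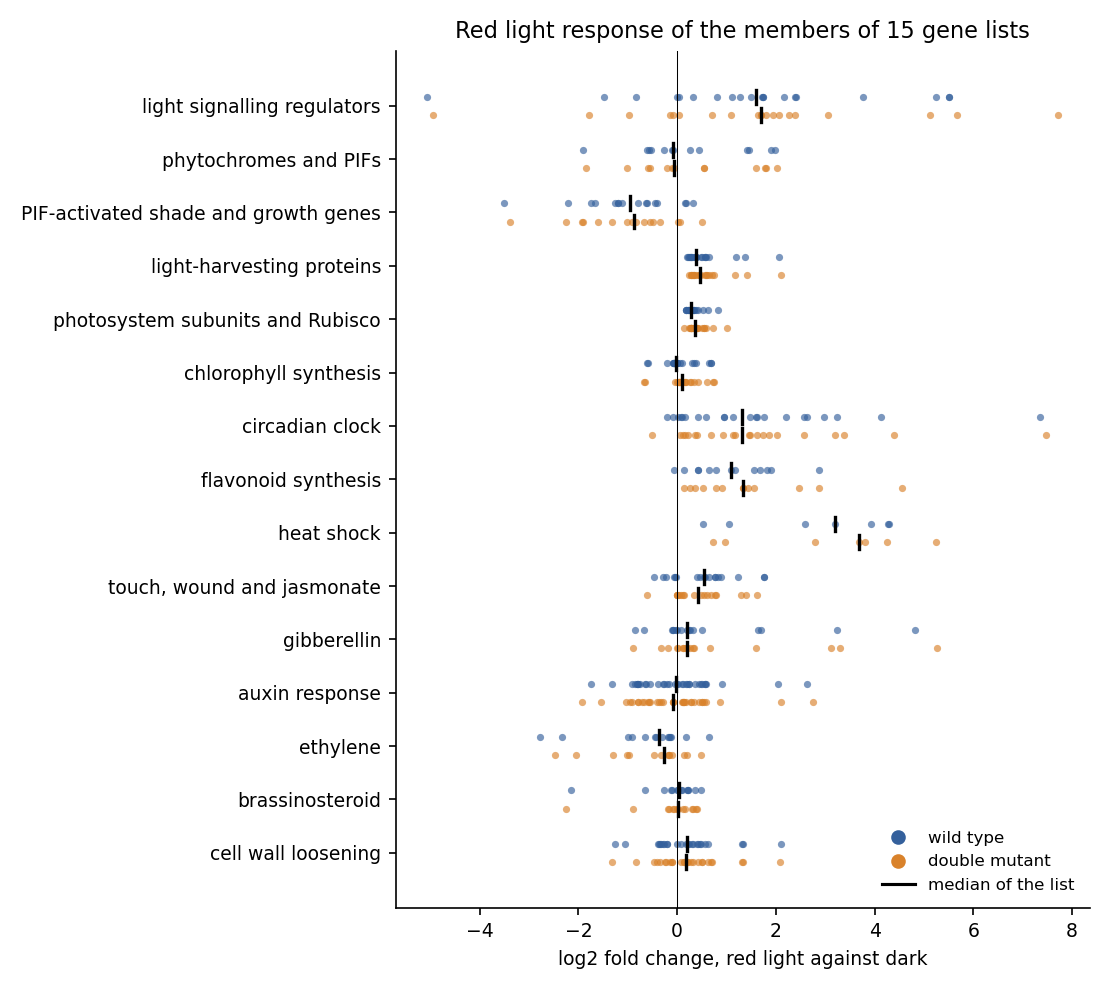
Log2 change with red light of each tested member of 15 gene lists in the wild type and the double mutant, with 1 point per gene and a line at each list's median. The heat shock list has the highest medians (3.19 and 3.69) and the PIF-activated list the lowest (−0.96 and −0.87).

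The third question was how the genotypes differ before any red light. Besides B''α, edgeR called 9 genes in the dark, which makes 5 higher and 5 lower in the double mutant. ILA (AT1G64790, chromosome 1, 24064822 to 24083428), a HEAT-repeat protein gene with roles in immunity, was 1.85-fold higher (33.5 ± 1.68 against 61.5 ± 5.52 CPM, SD, n = 3; log2 0.89 ± 0.11 SE, adjusted p = 1.80e-04). AT1G64795, whose annotated span from 24082579 to 24082848 lies within ILA, was at 0.794 ± 0.397 CPM in the wild type and 38.3 ± 2.42 CPM in the mutant (adjusted p = 4.01e-12). Whether counting used strand is not given in the sources used here, so it is uncertain which gene of this pair the reads of the shared region come from. The long non-coding RNA AT3G05945 (chromosome 3, 11510090 to 11510510) was 2.06-fold lower (log2 −1.04 ± 0.11, 50.9 ± 5.20 against 24.2 ± 2.57 CPM, adjusted p = 3.64e-05) and AT3G05730 1.401-fold lower (−0.49 ± 0.07, adjusted p = 0.00286). The starch-related gene QQS was at 8.70 ± 2.58 CPM in the wild type and 0.903 ± 1.04 CPM in the mutant (adjusted p = 0.00121), and AT1G75945 at 0.496 ± 0.560 and 5.89 ± 1.52 CPM (adjusted p = 0.00355). AT3G29970 was higher by 1.597 ± 0.27 on the log2 scale (edgeR adjusted p = 0.0145). AT1G64795, QQS, AT1G75945 and AT3G29970 were each chosen after its values were seen.

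Some of the dark calls ended when libraries were left out and the filter on low counts redone. AT3G29970 was not called without wild type dark replicate 1 or double mutant dark replicate 1 or 2 (0.0556 to 0.0877), without the 2 dark libraries that stand apart (0.104) or with limma-voom (0.0587). AT4G11393 (log2 1.21 ± 0.18, edgeR adjusted p = 0.00193) missed the threshold without the 2 dark libraries that stand apart (1.00, adjusted p = 0.0738). AT5G35940 (−1.15 ± 0.22, edgeR adjusted p = 0.0489) was called without wild type dark replicate 1 or double mutant dark replicate 3 and missed without any of the other 10 libraries in turn (0.0595 to 0.449), and also with DESeq2 (0.0571) and limma-voom (0.0655). Without wild type dark replicate 1 the genes higher in the mutant numbered 8, and without wild type dark replicate 2 the genes lower numbered 19. Without the filter on low counts 24 genes were higher and 45 lower. At an unadjusted p under 0.05 there were 743 genes, where 924 would pass by chance alone. Of the fixed lists, camera called photosystem genes lower (median −0.05, adjusted p = 0.00569), chlorophyll synthesis lower (−0.06, 0.00569), light-harvesting genes lower (−0.03, 0.0310) and root hair markers higher (0.20, 0.0310), each with adjusted p = 0.768 with an estimated correlation and with 0 members called by edgeR over all genes or over the list alone. Without the 2 dark libraries that stand apart, none of these 4 lists was called (0.245, 0.245, 0.420 and 0.657), and the root hair median was −0.01. Without double mutant dark replicate 3 alone they were not called either (0.830, 0.734, 0.734 and 0.830), nor without wild type dark replicate 2 (0.239, 0.425, 0.180 and 0.425). Of the other lists none was called by camera, and HY5 (−0.07 ± 0.11), PIL1 (−0.08 ± 0.17), PHYA (0.04 ± 0.07) and PIF4 (0.31 ± 0.17) did not differ at this depth (edgeR adjusted p = 1.00 each).

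The fourth question was how the genotypes differ after 1 h of red light, where edgeR called 10 genes higher and 5 lower in the double mutant. SPX1 (AT5G20150, chromosome 5, 6802282 to 6803655), a phosphate sensor gene induced by phosphate starvation, stood at 69.8 ± 6.71 CPM in the wild type and 130 ± 15.6 CPM in the mutant (SD, n = 3; 1.88-fold, log2 0.91 ± 0.12 SE, adjusted p = 2.83e-04), against 15.8 ± 3.61 and 13.4 ± 2.40 CPM in the dark. DIN2, a β-glucosidase gene known to rise in darkness, was 1.98-fold lower in the mutant (log2 −0.99 ± 0.13, 70.3 ± 6.37 against 35.6 ± 3.57 CPM, adjusted p = 4.93e-04), and AT5G35940 3.85-fold lower (−1.94 ± 0.24, adjusted p = 2.83e-04). AT3G05945 (−1.06 ± 0.11), ILA (0.77 ± 0.11), AT1G64795 (0.388 ± 0.349 against 30.6 ± 0.796 CPM), QQS (10.9 ± 2.59 against 1.26 ± 0.120 CPM), AT1G75945 (0.388 ± 0.349 against 4.73 ± 0.941 CPM), AT3G29970 (1.33 ± 0.25) and B''α differed in red light as in the dark, so that 8 of the 17 genes called in either condition were called in both with the same sign. The cutinase gene CDEF1, chosen after its values were seen, was higher by 0.51 ± 0.10 (adjusted p = 0.0494) and not called without any of 9 libraries in turn (0.0549 to 0.414).

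Of the 15 red light calls 7 ended when a single library was left out and the filter on low counts redone, CDEF1 among them. AT1G75945 was not called without any of the 3 wild type red libraries or double mutant red replicate 1 or 3 (0.0504 to 0.0845). AT3G29970 was not called without any of 8 libraries in turn (0.0549 to 0.469) or with DESeq2 (0.113). BAG7, an endoplasmic reticulum co-chaperone gene, stood at 287 ± 156 and 1148 ± 244 CPM (log2 2.004 ± 0.35, edgeR adjusted p = 0.0143) and was not called with DESeq2 (0.297) or without wild type red replicate 1 (0.182) or 3 (0.258) or double mutant red replicate 1 (0.0706) or 3 (0.108). SRG3, a glycerophosphodiesterase gene, was 1.89-fold higher (0.91 ± 0.16, edgeR adjusted p = 0.0161) and not called without wild type red replicate 1 (0.217) or 3 (0.211) or double mutant red replicate 1 (0.231) or 3 (0.103). Its annotated span overlaps that of AT3G02030 (0.79 ± 0.14, edgeR adjusted p = 0.0148), so it is uncertain which gene the reads of the overlap come from. AT3G02030 was not called without wild type red replicate 1 (0.0833), 2 (0.0906) or 3 (0.174) or double mutant red replicate 1 (0.220) or 3 (0.103). HSP90.1 was 1.53-fold higher (0.62 ± 0.12, edgeR adjusted p = 0.0494), with 35.9 ± 3.43 and 55.2 ± 6.16 CPM. It was not called with DESeq2 (0.191) or without any of 9 libraries in turn (0.0587 to 0.625). The count of genes higher fell to 5, 6 and 3 without wild type red replicate 1, 2 and 3, and to 4 without double mutant red replicate 1 or 3. Other settings called more genes, with 29 higher and 39 lower without the filter on low counts, 19 and 24 with only the 2 groups compared and 21 and 25 without the 2 dark libraries that stand apart. Of the fixed lists camera called only heat shock (median 0.15, adjusted p = 8.30e-04), with adjusted p = 0.380 with an estimated correlation, 0.159 without wild type red replicate 3 and 1 member called by edgeR over all genes and over the list alone, HSP90.1.

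**Figure D4:**
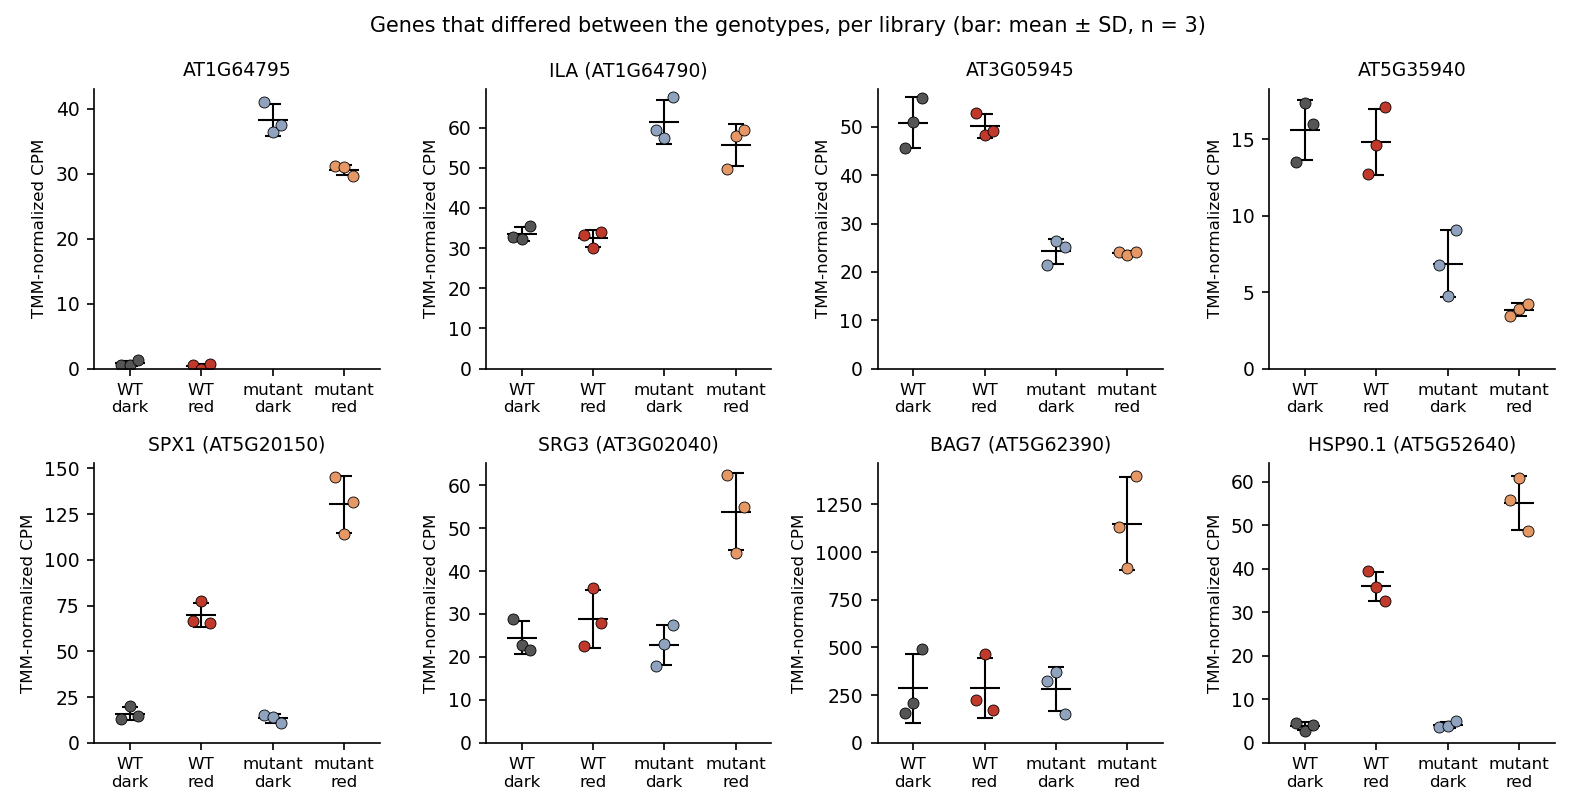
CPM per library (points) with the mean ± SD of each group (n = 3) for 8 genes called between genotypes in the dark or in red light: AT1G64795, ILA, AT3G05945, AT5G35940, SPX1, SRG3, BAG7 and HSP90.1. SPX1, BAG7 and HSP90.1 show their difference in red light, while ILA and AT3G05945 show it in both conditions.

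The last question was whether the response to red light itself differs between the genotypes. The sentinel genes of the response did not differ at this depth. The double mutant's log2 change minus that of the wild type was 0.01 ± 0.14 for HY5, 0.11 ± 0.45 for PIL1, −0.04 ± 0.35 for ATHB2, 0.04 ± 0.12 for ELIP1, −0.01 ± 0.12 for CCA1, 0.13 ± 0.12 for CHS, −0.05 ± 0.10 for PHYA and −0.39 ± 0.21 for PIF4 (SE, n = 3 per group). EdgeR called 0 genes in either direction, with 613 at an unadjusted p under 0.05 where 924 would pass by chance, and limma-voom called 0. Without the filter on low counts edgeR called 20 genes higher and 8 lower. DESeq2 called 1, SPX1 (log2 1.15 ± 0.24, adjusted p = 0.0299), which also had the smallest adjusted p with edgeR (1.16 ± 0.22, 0.491). Without the 2 dark libraries that stand apart edgeR called BAG7 (2.01 ± 0.31, adjusted p = 0.00160) and DIN2 (−1.02 ± 0.16, 0.00160), and without wild type dark replicate 1 alone it called 2 genes higher and 1 lower. SPX1, BAG7 and DIN2 were here chosen after their values were seen. On simulated data the test recovered 47.8% of 2-fold and 83.3% of 4-fold interactions, so smaller differences were mostly out of reach. The simulated counts held no light response and their genes varied independently, so recovery in the real libraries was not measured and may be lower.

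Genes that answered red light by at least 1 on the log2 scale, picked by the mean response of both genotypes, were then compared as sets. The 739 raised genes had median responses of 1.45 in the wild type and 1.46 in the double mutant, a median interaction of 0.00 and 367 members (49.7%) with a smaller response in the mutant. Neither fry nor camera called this set. For 454 of them (61.4%) the 95% interval of the interaction lay within 1 of 0 on the log2 scale. The 233 lowered genes had median responses of −1.27 and −1.37 and a median interaction of −0.08. It was called by fry (p = 0.0169) and camera (p = 0.0101, and p = 0.00942 with an estimated correlation), while in a permutation of the libraries 17 of 100 splits gave a median at least as far from 0. The response was smaller in the mutant for 95 of these genes (40.8%), and the interval lay within 1 of 0 for 103 (44.2%). The permutation gave no call, and that of fry was lost with DESeq2 (p = 0.0505) and limma-voom (0.0509). It was also lost without wild type dark replicate 1 (−0.05, 0.132) or 2 (−0.07, 0.192) or wild type red replicate 1 (−0.03, 0.245), 2 (−0.05, 0.233) or 3 (−0.05, 0.109). The genes were picked anew each time, and with a wild type library missing the picking itself can move the median toward 0. The losses without a library therefore cannot be tied to that library.

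Of the fixed lists, camera called a more positive response in the double mutant for photosystem genes (median interaction 0.08, adjusted p = 1.52e-04). Camera also did so for light-harvesting genes (0.06, 0.00450) and chlorophyll synthesis (0.09, 0.0237), a list that was mixed in the wild type. Each list had adjusted p = 0.780 with an estimated correlation and 0 members called by edgeR over all genes or the list alone. These are the lists that were called lower in the mutant in the dark. The photosystem list was not called without double mutant dark replicate 3 (0.03, adjusted p = 0.525) or red replicate 2 (0.05, 0.0753). The light-harvesting list was not called without wild type red replicate 1 (0.0688), double mutant dark replicate 2 (0.199) or 3 (0.525), double mutant red replicate 2 (0.254) or both dark libraries that stand apart (0.0887). Chlorophyll synthesis was not called without wild type dark replicate 2 (0.450), wild type red replicate 2 (0.106) or 3 (0.288), double mutant dark replicate 2 (0.105) or 3 (0.535), double mutant red replicate 2 (0.254) or both dark libraries that stand apart (0.437). It was not called either with all libraries thinned to the smallest total (0.0657). Camera called no other list, among them clock (−0.01), flavonoid (0.11) and heat shock genes (0.20).

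Averaged over genotypes, 2759 genes rose with red light and 1843 fell, and all 26 photosystem genes and all 7 heat shock genes were among those that rose (26 and 7 adjusted over the list alone). Averaged over light, 10 genes were higher and 12 lower in the double mutant (edgeR, adjusted p under 0.05). B''α (−2.50 ± 0.12), AT3G05945 (−1.05 ± 0.08), ILA (0.83 ± 0.08), QQS and AT5G35940 (−1.55 ± 0.16) had the smallest adjusted p after AT1G64795. Called by this average and in neither condition alone were, among others, the defensin-like gene LCR67 (0.94 ± 0.14, adjusted p = 0.00208) and LEA4-5, a late embryogenesis abundant protein gene (−1.69 ± 0.33, adjusted p = 0.0419), both chosen after their values were seen. The call of LEA4-5 ended with DESeq2 (0.201), limma-voom (0.389) and without any of 9 libraries in turn (0.0533 to 0.135). The lower genes numbered 27 without wild type dark replicate 2 and 6 or 7 without any 1 of 7 others, namely wild type red replicates 2 and 3, double mutant dark replicates 1 to 3 and double mutant red replicates 1 and 2. Camera called ethylene genes lower (median −0.10, adjusted p = 0.0206) and root hair markers higher (0.32, 0.0116) in the mutant on average, each with adjusted p = 0.858 with an estimated correlation and 0 members called by edgeR over all genes.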

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

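Of the tests in this part, those without the 2 dark libraries that stand apart and with all libraries thinned to the smallest total were chosen only after the data had been seen.

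The 233 genes lowered by red light had a median interaction of −0.0794, picked out because the test of the difference between the genotypes' responses passed (fry p = 0.0169), while in a permutation of the libraries 17 of 100 splits gave a median at least as far from 0. Without the 2 dark libraries that stand apart the median was −0.0946 and still called. Without wild type dark replicate 1 alone, which is among them, the call ended, so these libraries are not excluded as its source. Unequal depth is argued against, since with all libraries thinned to the smallest total the median was −0.0736 and still called. Chance cannot be excluded at 17 of 100 splits, the highest of the others at 0.130. The call by fry also ended when DESeq2 or limma-voom chose the lowered genes. It ended too without any of 5 wild type libraries, where the same limit on picking genes anew holds. A stronger lowering of these genes by light when B''α and B''β are disrupted therefore stays an open possibility that these libraries could not settle, with 95 of the 233 genes (40.8%) pointing the other way.

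Light-harvesting genes had a median interaction of 0.0618 (camera adjusted p = 0.00450), picked out by the same test of the difference between responses. Photosystem and Rubisco genes had a median interaction of 0.0800 (camera adjusted p = 1.52e-04), and chlorophyll synthesis genes 0.0895 (camera adjusted p = 0.0237), each picked out in the same way and each not called with an estimated correlation (adjusted p = 0.780).

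Other splits of the libraries were fitted for every count of called genes. For the red light responses of the wild type (2819 genes) and the double mutant (2958 genes), 1 of 10 splits of the 6 libraries gave as many, the real one, and the highest other gave 0; for the genotype difference in red light (15 genes) it was again 1 of 10 with 0 as the highest other. For the genotype difference in the dark (10 genes) 3 of 10 splits gave as many, the highest other 252. Both of those other splits put wild type dark replicate 1 and double mutant dark replicate 3 in 1 group, which points to a structure of the dark libraries beside genotype. With 10 splits no share under 0.05 can be had for these 4 counts. For the mean red light response (4602 genes) 1 of 100 splits gave as many and the highest other gave 1, so chance is excluded. For the mean genotype difference (22 genes) 7 of 100 gave as many, the highest other 393, so chance cannot be excluded. As many were given by 6 of the 38 other splits that kept those 2 dark libraries together and by 0 of the 61 that parted them; without both libraries edgeR called 19 genes higher and 17 lower. For the interaction (0 genes by edgeR, 613 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom) 100 of 100 splits gave as many, the highest other 268. That share was fixed in advance, since no split can call fewer than 0 genes, so it says nothing on chance.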

How the results depend on the processing

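The settings without the 2 dark libraries that stand apart and with all libraries thinned to the smallest total were chosen after seeing the data. All others were planned. No named gene or list called under 1 setting was called in the opposite direction under another. Among counts of calls, medians and targeted genes, all 20 kept their side of the threshold (counts within 1.5 times) with RLE factors, and 18 of 18 with thinned libraries. With DESeq2 the interaction had 1 gene higher (0 with edgeR) and the median interaction of lowered genes was −0.0872 and no longer called. With limma-voom it was −0.0698 and not called either. For these medians fry was run on voom values with TMM factors under every setting. DESeq2, limma-voom and RLE factors changed only the genes in the set and the median. Without the filter on low counts calls were 24 higher and 45 lower for genotype in the dark (5 and 5 with the filter), 29 and 39 in red light (10 and 5) and 20 and 8 for the interaction (0 and 0). They were 47 and 69 for the mean genotype difference (10 and 12). B''β passed in the dark (−1.86). With a mean of at least 5 CPM the mean genotype difference had 7 genes lower. With only the 2 groups compared, genotype in red light had 19 higher and 24 lower. Without the 2 dark libraries that stand apart it had 21 and 25, the interaction 1 and 1, and the mean genotype difference 19 higher. The cause was not tested for any of these changes.

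Replicates share numbers across groups, and a fit with the replicate number as a replicate block gave 6 genes higher for genotype in red light and 6 lower for the mean genotype difference, with the other counts within 1.5 times. It also ended the calls of SRG3 and HSP90.1 between genotypes in red light, of BRI1, HMGS and PCK1 in the wild type response, of PP2AA3 in that of the double mutant and of the light-harvesting and root hair lists in the dark. Libraries with the same number showed little likeness. Of 18 such pairs, 2 had correlated deviations over 0.1 (−0.170 to 0.150), and 2 of 12 libraries matched their own number best. The labels do not say whether a number marks a shared day, and with 3 libraries per group these correlations cannot exclude it.

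With each library left out in turn, calls ranged from 4 to 8 higher and 4 to 19 lower for genotype in the dark, 3 to 11 higher and 5 to 7 lower in red light, 0 to 2 higher and 0 to 1 lower for the interaction. They ranged from 7 to 13 higher and 6 to 27 lower for the mean genotype difference. The median interaction ranged from −0.121 to −0.0312 for lowered genes and from −0.0287 to 0.0389, on both sides of 0 and never called, for raised genes. The wild type response ranged from 1618 to 2137 higher and 598 to 922 lower, that of the double mutant from 1678 to 2123 and 686 to 1060, and B''α from −2.32 to −2.15 in the dark and −2.82 to −2.71 in red light. The share of raised genes with a smaller response in the mutant, 49.7% over all libraries, was 54.1% without wild type dark replicate 2, 53.5% without wild type red replicate 2 and 44.6% without double mutant dark replicate 2. For these medians and shares the genes were picked anew without each library. A missing wild type library itself favours smaller mutant responses among the picked genes, and a missing mutant library larger ones. These shifts therefore cannot be tied to single libraries.

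Of 105 list results, 12 lost their call with an estimated correlation, 8 lost and 2 gained one without the 2 dark libraries that stand apart, 3 lost one with thinned libraries. The root hair median in the dark turned from 0.20 to −0.01 without those 2 libraries. Of the results for genes named by the fixed rule, 9 lost their call with DESeq2 and 1 with limma-voom. Genes chosen after their values were seen are not in these numbers. A filter leaving out chloroplast and mitochondrial genes was not run, since the table holds no such loci. DESeq2 and limma-voom were not run for the list tests. B''β gave no value with a mean of at least 5 CPM or thinned libraries. The median standard error was 0.173 to 0.174 for a difference of groups and 0.247 for the interaction.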

Other observations

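The gene lists of this part, the placement tests, the heat tests and the test of phosphate genes on the interaction were chosen only after the results they concern had been seen. The test of the wider phosphate list in red light was laid down before its result was seen, on a list drawn up after the data.

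Regulators of greening rose with red light in both genotypes. In the wild type 6 of 10 sigma factor and greening genes rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0357 with an estimated correlation). The double mutant also had 6 higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.0245 with an estimated correlation). SIG5, a plastid sigma factor known to respond to light and stress, rose by 3.69 ± 0.15 in the wild type and 3.82 in the double mutant, GLK2 by 1.82 ± 0.09 and GNC by 1.17 in the wild type. Of 13 carotenoid genes 4 rose and 0 fell in the wild type (5 adjusted over the list alone; camera adjusted p = 0.0424 with an estimated correlation) and 5 rose in the double mutant (7 adjusted over the list alone). ABA1, the zeaxanthin epoxidase gene, rose by 1.80 ± 0.11 and PSY, the entry enzyme, by 0.77. In the wild type 2 of 8 plastid isoprenoid genes rose, DXS (0.38) and HDR (0.23), and 1 of 9 genes of the unfolded protein response, with no call for either list (camera adjusted p = 0.292 each). In the double mutant camera called the isoprenoid list higher (adjusted p = 0.0399, and adjusted p = 0.108 with an estimated correlation) and not the unfolded protein list (adjusted p = 0.186).

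Part of the list of abscisic acid signalling and late embryogenesis genes also rose with red light: 7 of 15 in the wild type (8 adjusted over the list alone, camera adjusted p = 0.0424 with an estimated correlation) and 8 in the double mutant (10 adjusted over the list alone), with 0 lower in either. In the wild type the late embryogenesis gene LEA76 overlapped between dark (4.41 to 58.2 CPM) and red light (7.59 to 50.4 CPM). So did ABR (16.5 to 128 and 20.6 to 101 CPM). In the wild type ABF3 rose by 1.85, the phosphatase gene HAB1 by 1.44 and NCED3, a synthesis gene, by 1.29. In the dark these genes were lower in the double mutant by camera (adjusted p = 1.27e-05), with adjusted p = 0.138 with an estimated correlation, 7 lower adjusted over the list alone and 0 over all genes by edgeR. In red light they were also lower there by camera (median −0.47, adjusted p = 0.0197 with an estimated correlation), with 1 lower adjusted over the list alone and no call by fry (adjusted p = 0.0779). There the wild type values of LEA7 were 33.6 CPM in replicate 2 against 8.82 and 7.19 CPM in the others, and the test was not run without that library. In the dark LEA4-5 stood at 74.1, 10.2 and 20.04 CPM in the wild type dark libraries and at 5.76, 6.52 and 4.54 CPM in those of the double mutant. The highest value is in wild type replicate 1, which stands apart.

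The 25 genes other than B''α called between genotypes in the dark, in red light or on average formed 12 pairs within 1 Mb of each other, against a median of 6 for random sets of tested genes. Of 10000 random sets 224 had as many pairs. AT3G29644, AT3G05945, AT3G29970 and QQS start within 850 kb on chromosome 3, so each pairs with each of the others. Their annotated spans do not overlap. AT3G29644 was chosen after its values were seen. Overlapping gene models may account for part of this: with 1 gene of each overlapping pair left out, 648 of 10000 random sets had as many as the 9 pairs that remained, so chance placement is not excluded. Linkage within 2 Mb of the disrupted genes is argued against as the source of these pairs, since 0 of their members lay within 2 Mb of B''α or B''β. Of the 25 genes 1 lay there, and 8488 of 10000 random sets had as many. Longer linked segments were not tested. Other sequence or insertion differences between the lines were not tested and stay open.

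Heat shock genes rose with red light in both genotypes. The median mean level of 9 small heat shock genes in red light, HSP17.8 added after a first look at the other 8, was 0.840 CPM in the wild type and 0.931 CPM in the double mutant (1.504 and 0.621 CPM in the dark), close to the 3 count limit. In the wild type HSP17.8 went from 1.56 to 24.6 CPM with red light, HSP17.4 from 2.75 to 5.61, HSP15.7 from 5.81 to 8.42 and HSP22 from 1.77 to 0.840. No sample under known heat stress gives a level to compare, so heat stress is not excluded, and slight warming under the lamp cannot be told apart from light itself, with 5 of 7 tested genes of the list higher in the wild type. The rule for reading the warming test was reworded after its value was seen, and a response of these genes to red light alone stays open.

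SPX1, PS2 and SRG3, all known to be induced by phosphate starvation, were 3 of the 4 genes with the smallest p in the interaction (SPX1 1.16 ± 0.22, edgeR adjusted p = 0.491; the others 1.00). With red light 2 of 14 phosphate genes rose in the wild type, SPX1 (2.16 ± 0.15) and PAP17 (2.24 ± 0.18), and 6 in the double mutant, among them SPX1 (3.32), PS2 (2.96, with 0.339 to 0.987 CPM in its dark libraries, close to the 3 count limit) and SQD2 (0.46). SPX1, PS2 and SRG3 prompted the list, and without them 1 of 11 rose in the wild type and 3 in the double mutant. A wider phosphate starvation response in the double mutant in red light stays open as a possible source: without those 3 genes the other 11 had a median genotype difference in red light of 0.20 (fry adjusted p = 0.0175; camera adjusted p = 0.0197 with an estimated correlation). In the dark their median was 0.17, of similar size, without a call (camera adjusted p = 0.109), so the shift cannot be tied to red light. Whether it depends on light was not settled, since the median interaction of the same 11 genes was 0.0206 (fry adjusted p = 0.686). Listed genes with too few counts to be tested do not enter these numbers. In the double mutant in red light, IPS1 (0.250 to 0.687 CPM), SPX3 (0 to 0.749 CPM) and NPC4 (0.229 to 0.554 CPM) were among them. These stayed close to the 3 count limit there.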
